A study of Mus musculus with 4 samples.

How the data were processed

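Gene expression was measured in Lin-Sca-1+c-Kit+ (LSK) bone marrow cells, the fraction that holds hematopoietic stem cells and multipotent progenitors, from lethally irradiated mice that had received fetal liver cells of 1 of 4 genotypes. Each genotype (WT, TET2KD, JAK2V617F and double mutant) was represented by 1 array. The design text gives 5 mice per genotype; whether their cells were pooled before RNA extraction is not stated in the sources used here. Per the labels' protocols, RNA was extracted with Trizol, amplified with the NuGEN Ovation Pico WTA system and labelled with Cy3 by the Agilent enzymatic kit for DNA, for hybridisation to a 1-colour Agilent mouse array.

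Per the file headers, the deposited intensity values came from Agilent Feature Extraction 10.7.3.1, which had subtracted background and detrended each array on its own without scaling arrays to each other. The deposited mean and local background intensity of each spot were used only in the normexp alternative. The deposited series matrix holds log2 values: set against the scanner values, each of its columns equalled log2 of the processed signal minus a constant, with 0 of 55665 probes off by more than 0.001, so its scale is log2, arrays were shifted and genes were not centred. Its column medians were -2.64 for WT, -2.63 for TET2KD and -2.60 for both JAK2V617F and the double mutant. All 4 arrays lay on 1 slide and were scanned in 1 session, so slide and scan do not separate the groups. The build of the probe coordinates is mm9, per the file headers.

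Each array has 62976 spots, of which 59305 are not controls and represent 55681 probes. Signals were taken to log2 and the array's 75th percentile over non-control spots was subtracted. Spots flagged as outliers were dropped (162 to 199 per array), spots of 1 probe were averaged, and then the probes of 1 gene. Of the probes, 28026 were named by accession, 3418 by symbol and 295 by an unambiguous synonym through a RefSeq gene table of assembly GRCm38, used for names only; 23942 stayed without a gene. The named probes covered 22563 genes, of which 7115 had at least 2 probes. No spot was saturated. Between 49.4% (TET2KD) and 54.7% (JAK2V617F) of spots were well above background, which with 1 array per group limits the precision.

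A gene entered a comparison when a probe was well above background in at least 1 of its 2 arrays. Where a probe was not well above background in 1 of them, that side was set to the lowest signal among well-above-background spots of that array, or its own signal if higher. The fold is given as "at least" where this holds for every compared probe of the gene, and for some genes where it holds for 1 of them. Other genes that average such a probe with a measured one have plain folds, which rest in part on the floor. With 1 array per group there is no replicate check: the comparisons of 2 arrays carry no p-value, and "higher" and "lower" describe these arrays. A gene was counted when it differed at least 2-fold. Of 34 gene lists fixed before the data were examined, 33 had at least 3 measured members. A list is described by its median log2 difference and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins; genes of a list are not independent, so a percentile describes these arrays only. List medians outside the central 95% of random lists are called outside the range.

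Genes were named by a rule fixed at the same time. Tet2 and Jak2 come first. Then come the 10 largest differences each way for each mutant against WT and the 8 largest each way between the double mutant and each single mutant, over genes with every compared probe well above background in both arrays, with the brighter array at or above its 75th percentile, all probes of 1 sign, and a 2-fold difference with normexp too. Up to 4 genes each way per comparison that were below background in 1 array were added, with up to 6 each way for the interaction (double mutant minus TET2KD minus JAK2V617F plus WT) and the 2 to 4 members with the largest difference of each list described. Unnamed gene models and immunoglobulin and T cell receptor segments were left out. The text names part of these genes; genes chosen in another way are marked as such.

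The alternatives were normexp background correction with an offset of 50, quantile scaling, scaling to the median of detected probes, cyclic loess, only probes above background on both arrays, no filter on dim probes, the brightest probe per gene, the series matrix values and a 3-fold threshold. A list test with 1 probe drawn per gene and a limma fit of additive TET2KD and JAK2V617F effects over the 4 arrays, with the spread pooled over genes and the Benjamini-Hochberg adjustment, were added after seeing the data, as was a check of how the counts depend on the floor. The steps were tested on simulated arrays of the TET2KD and WT comparison over 14314 genes: 200 of 200 genes planted 4-fold apart were recovered with 1 other gene called, and a list shifted by 0.5 had a median of 0.55 at percentile 100. Of 2000 lists with no planted shift, 117 (5.85%) lay outside the 95% range. The first 200 of them, drawn alone at first, had given 18. The simulated arrays shared 1 mean signal per spot. Beyond the planted shifts they differed only by a constant per array and by noise about as small as that between repeated spots. The real log2 differences of TET2KD against WT had an SD of 1.21. These figures therefore check the steps and do not give the accuracy on the real arrays. Computation used R 4.3.3 with limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.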

Results

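LSK cells were profiled on 4 arrays, 1 each for recipients of WT, TET2KD, JAK2V617F and double mutant fetal liver cells. TET2KD cells carried a knock-down of TET2, an enzyme that oxidises 5-methylcytosine, and JAK2V617F is the activating kinase mutation of myeloproliferative neoplasms, carried here as a transgene. Cells were collected 16 weeks after transplantation for WT and JAK2V617F, 13 weeks for the double mutant and 10 weeks for TET2KD, so that only JAK2V617F and WT shared a time. The 75th percentile of the signal was 128 in WT, 120 in TET2KD, 130 in JAK2V617F and 144 in the double mutant.

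Tet2 was lower than in WT in both groups that carry the knock-down on 2 of its 3 probes. On the probe at chromosome 3, 133126905 to 133126964 (mm9), the TET2KD array had 27.3% of the WT signal, the double mutant 60.3% and JAK2V617F 73.1%. On the probe at 133126751 to 133126810 the values were 56.3%, 61.6% and 105%. These probes lie within 214 bases of each other. The remaining Tet2 probe (133176421 to 133176479) was above background only in the double mutant, at least 2.36-fold higher than in WT. Jak2 was read by 1 probe (chromosome 19, 29387487 to 29387546), at 110% of WT in TET2KD, 95.8% in JAK2V617F and 106% in the double mutant; whether it reads the transgene is not known, so it checks nothing. Socs2, a feedback inhibitor induced by JAK-STAT signalling, was not well above background in WT on any probe. It was at least 11.1-fold, 15.9-fold and 34.1-fold higher in JAK2V617F on 3 probes within 462 bases, and at least 6.96-fold, 8.10-fold and 22.2-fold higher in the double mutant. A probe for Socs2 elsewhere stayed below background on all 4 arrays. The STAT5 target list as a whole was inside the range of random lists in both groups (median 0.34, percentile 94.6 in JAK2V617F; 0.06, percentile 66.5 in the double mutant).

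The only direct measure of error is the spread of repeated spots within an array, which had an SD of 0.156 (WT), 0.152 (TET2KD), 0.162 (JAK2V617F) and 0.165 (double mutant) on the log2 scale. It leaves out amplification, sorting and animals. A second measure set 2 probes of the same transcript against each other. In TET2KD against WT their log2 differences had a Spearman correlation of 0.78 over 245 pairs under 100 bases apart, and of 0.06 over 1344 pairs at least 500 bases apart. In JAK2V617F against WT the values were 0.78 and 0.11, and in the double mutant against WT 0.75 and 0.09. These correlations run across genes, which are not independent replicates. Where the first of 2 distant probes differed 2-fold, the other had the same direction in 51.6%, 58.5% and 55.6% of cases. Most genes have 1 probe, so a fold of a single gene below describes that probe's stretch of the transcript; list medians combine many genes.

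**Figure D1:**
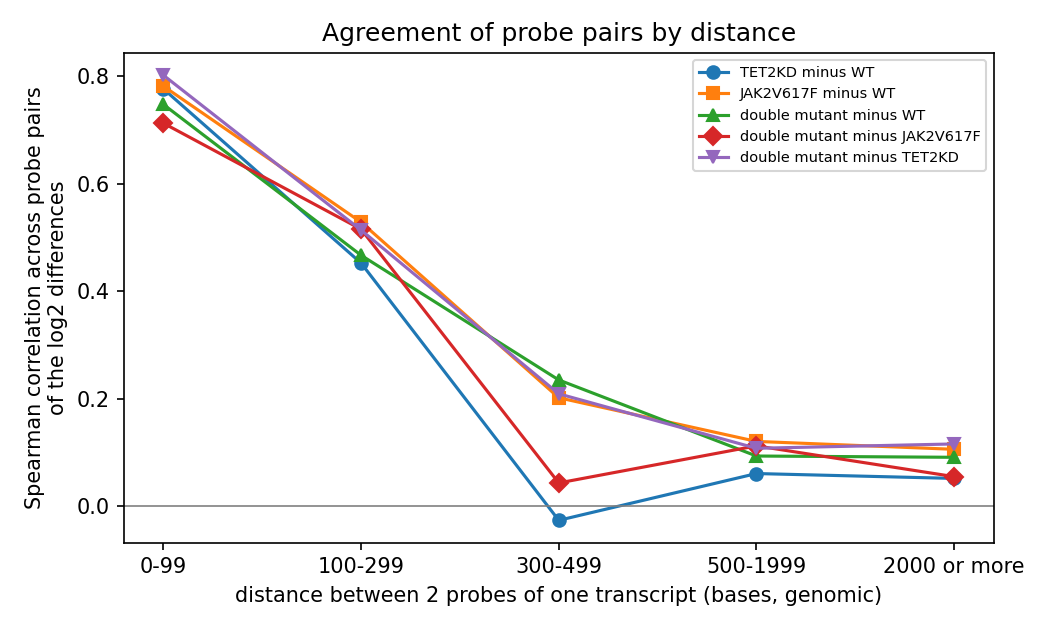
Spearman correlation, across pairs of probes of one transcript, of the log2 differences in each of the 5 comparisons (y axis) against the distance between the probes in bases on the genome (x axis). In TET2KD minus WT it is 0.78 under 100 bases and 0.05 at 2000 bases or more.

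The TET2KD array was compared with WT to describe LSK cells with reduced TET2 alone. Genes of granulocyte and monocyte progenitors and of mature neutrophils were higher, and genes of mitochondrial respiration were lower. Elane, which encodes neutrophil elastase, was 6.27-fold higher and Igsf6 5.02-fold, while F13a1 was at least 13.5-fold higher; the progenitor list had 7 of 19 measured members at least 2-fold higher and 2 lower, with a median of 0.81 (percentile 100). Ly86 of the same list was at least 6.17-fold lower. Among mature neutrophil genes 8 of 16 were at least 2-fold higher, with Ltf 8.62-fold and Chil3 6.37-fold higher and Il1r2 3.14-fold lower (median 1.02, percentile 100). Respiratory chain genes had a median of -0.44 (percentile 0.19), with Ndufa2 2.79-fold, Uqcrc1 2.35-fold and Uqcrfs1 2.33-fold lower and 0 of 39 higher.

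Other lists stood outside the range in TET2KD against WT. Plasma cell genes had a median of 1.51 (percentile 99.9), led by Tnfrsf17, at least 16.2-fold higher, and Jchain, 6.74-fold higher; this median of 9 genes ran from 0.70 with normexp to 2.62 with no filter on dim probes. The macrophage and dendritic cell list was at 0.64 (percentile 99.5), with Cd14 at least 7.64-fold higher. Megakaryocyte and platelet genes had a median of 0.53 (percentile 99.2): Vwf was 9.83-fold and Pf4 3.25-fold higher, while Gata1 was 25.8-fold lower; with no filter on dim probes the median was 0.01 (percentile 64.8). Immediate early genes were at 0.30 (percentile 99.9), with Egr2 at least 13.1-fold higher and Egr3 4.04-fold lower. Endothelial and stromal genes were at 0.63 (percentile 97.8), with Emcn 9.04-fold higher, a position kept under 5 of 8 alternatives. STAT5 targets were at 0.38 (percentile 97.6), a position kept under 2 of 8 alternatives. Socs3 was 3.84-fold and Cish 3.44-fold lower. Bcl2l1 was 6.45-fold higher as an average of 2 probes that disagree. Of these, 1 was not above background in WT, and over the other Bcl2l1 was lower (-0.62 on the log2 scale). Ribosomal protein genes were at -0.25 (percentile 1.13), with Rpl13a 2.06-fold lower, but inside the range with no filter on dim probes (percentile 7.36).

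Among genes above background in both arrays and meeting the naming rule, the largest single differences of TET2KD against WT were Med13l (81.8-fold), Hdac8 (34.1-fold) and Slc4a1, the red cell anion exchanger (23.6-fold), on the higher side. On the lower side they were Dcakd (34.5-fold), Mrpl58 (31.9-fold), the B cell receptor component Cd79a (31.4-fold), Rab4b (27.0-fold) and Klhl12 (26.2-fold). The folds of Hdac8 and Cd79a leave out a probe not above background in either of these 2 arrays. With a probe detected only on another array set to the floor, the scaled log2 signal of Hdac8 averaged -1.35 in WT and 1.31 in TET2KD. That of Cd79a averaged 0.52 and -1.86. Among genes below background in 1 array, Tlcd3a and Lfng were at least 67.6-fold and 60.7-fold higher, and Dph6 and Tac4 at least 63.1-fold and 38.9-fold lower. In all, 2277 genes were at least 2-fold higher and 2502 lower among 14314 compared. With normexp the counts were 796 and 1082 and with the series matrix values 2218 and 3086, and weeks after transplantation differed between these 2 arrays.

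The JAK2V617F array was compared with WT at the same 16 weeks. Granulocyte and monocyte progenitor genes and cell cycle genes were higher, and stem cell and mature neutrophil genes lower. Ctsg was 9.80-fold, the myeloid transcription factor Cebpa 6.55-fold and Prtn3 5.82-fold higher, and the progenitor list had 9 of 19 members at least 2-fold higher and 0 lower (median 0.56, percentile 99.7). The stem cell list had 13 of 29 members at least 2-fold lower and 3 higher (median -0.50, percentile 0.66). Txnip was 6.12-fold, Sult1a1 at least 5.10-fold and Prdm16 at least 4.41-fold lower, and Nupr1 5.74-fold higher. S phase genes had a median of 0.46 (percentile 99.7), with Mcm10 3.33-fold and Rfc4 2.83-fold higher and Cdc6 2.91-fold lower.

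Genes of G2 and mitosis had a median of 0.61 (percentile 99.9), with Ccna2 2.67-fold higher and Foxm1 2.96-fold lower. Mature neutrophil genes were at -0.81 (percentile 0.61), with Lcn2 8.98-fold lower. Inflammatory cytokine genes were at 0.71 (percentile 99.7): Cxcl2 was 6.95-fold and Tnf at least 14.6-fold higher, and Relb 8.25-fold lower. Over probes above background on both arrays this list's median was 0.30 (percentile 91.9) and that of p53 targets 0.31 (percentile 94). Glycolysis and hypoxia genes were at 0.39 (percentile 99.5), led by Vegfa (8.32-fold higher), but inside the range with the brightest probe (0.22, percentile 95.8), and respiratory chain genes at 0.22 (percentile 98.8), led by Ndufb8 (3.36-fold higher). p53 targets were at 0.59 (percentile 98.3), with Pmaip1 22.6-fold higher and Polk 17.9-fold lower. Apoptosis regulators were at -0.65 (percentile 0.49), with Bcl2a1d at least 17.3-fold lower and Birc3 6.84-fold higher. Cytokine receptors were at -0.42 (percentile 1.25): Il3ra was 5.47-fold and Flt3 4.16-fold lower, and Il1rl1 at least 6.43-fold higher; with the brightest probe the list was inside the range (-0.34, percentile 3.94).

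Among the largest single differences of JAK2V617F against WT, with the same limits, were Ufsp1 (46.0-fold), Dgat1 (36.2-fold), Med13l (34.1-fold) and Pcif1 (28.2-fold) on the higher side, and Bcas3os2 (36.0-fold), Slc2a4rg-ps (34.3-fold), Gng11 (33.9-fold) and the eosinophil ribonuclease gene Ear2 (22.7-fold) on the lower side. Below background in 1 array, Bsn was at least 61.4-fold higher, and Tie1 and the telomerase gene Tert were at least 49.8-fold and 39.7-fold lower. In all, 2309 genes were at least 2-fold higher and 2342 lower among 14895; with normexp the counts were 886 and 910.

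The double mutant array differed from WT most clearly in myeloid progenitor genes. Of 19 granulocyte and monocyte progenitor genes, 13 were at least 2-fold higher and 0 lower (median 1.70, percentile 100). F13a1 was at least 31.6-fold, Igsf6 12.7-fold, Ctsg 12.1-fold and the Fc receptor gene Fcgr3 7.93-fold higher. The stem cell list had 13 of 28 members at least 2-fold lower and 1 higher (median -0.83, percentile 0.01), among them Txnip (10.8-fold) and Meis1 (7.86-fold). The Hoxa and cofactor list, which shares 2 genes with other lists, was at -0.99 (percentile 1.33), with Hoxa9 4.12-fold lower and Hoxa10 at least 3.63-fold higher; it was inside the range with no filter on dim probes (-0.77) and with the brightest probe (-0.62).

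**Figure D2:**
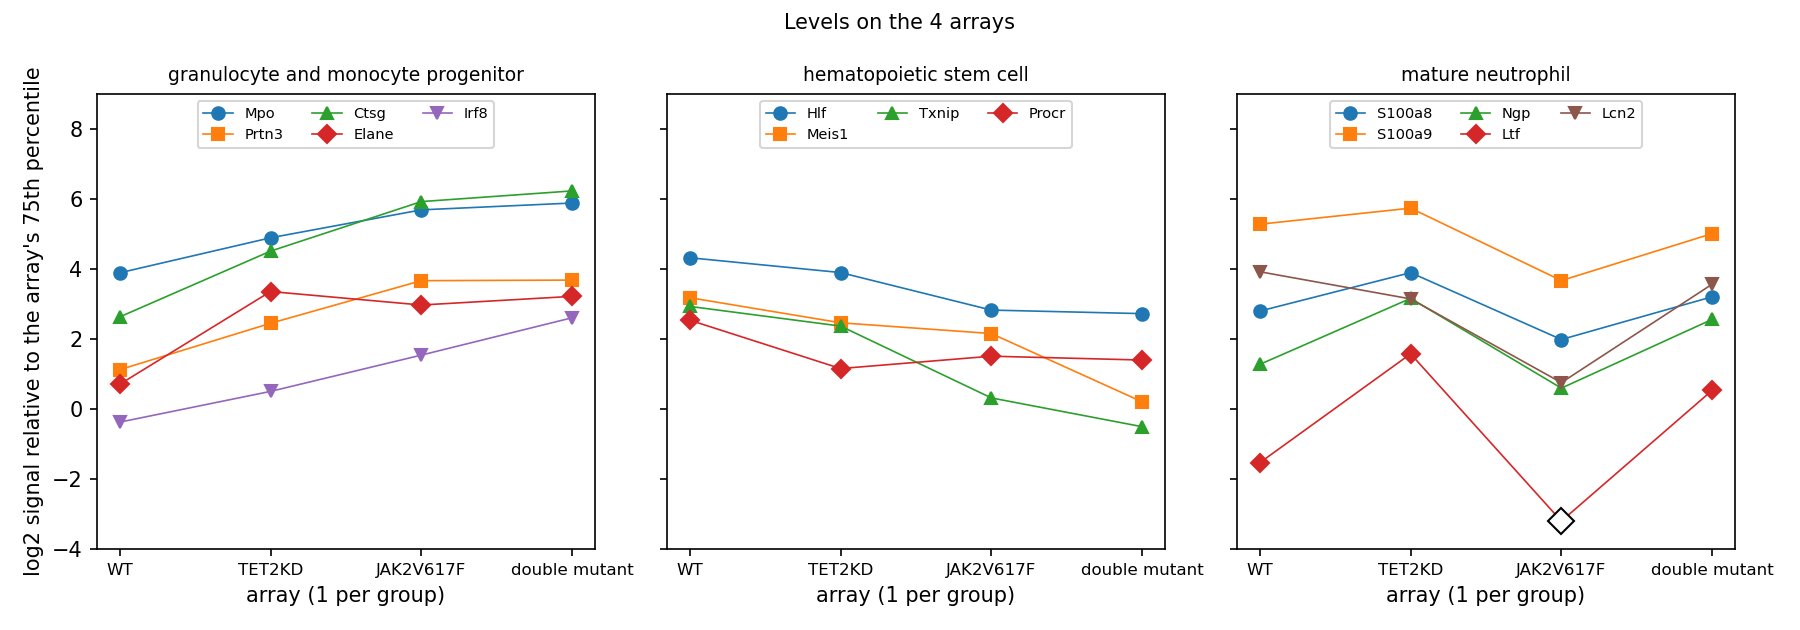
Scaled log2 signal (y axis) of 4 or 5 genes from each of 3 lists on the 4 arrays (x axis, 1 array per group; lines only link a gene's points, and the open symbol is a value not well above background). Mpo, Prtn3, Ctsg and Irf8 were lowest in WT, and Hlf and Txnip highest in WT.

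Mature neutrophil genes were at 0.67 in the double mutant against WT (percentile 99.6), with Ltf 4.18-fold and Chil3 4.07-fold higher. Plasma cell genes were at 1.09 (percentile 99.8), with Jchain 4.67-fold higher (0.39 with normexp, 2.22 with no filter on dim probes). Inflammatory cytokine genes were at 0.81 (percentile 100), with Cxcl2 6.82-fold and Tnf at least 23.1-fold higher. S phase genes were at 0.50 (percentile 99.9) and those of G2 and mitosis at 0.36 (percentile 98.4), with Mcm10 2.89-fold and Kif11 2.78-fold higher and Cdc20 2.88-fold lower. Glycolysis and hypoxia genes were at 0.39 (percentile 99.7), with Vegfa 6.78-fold higher, respiratory chain genes at 0.16 (percentile 98.8), with Ndufa5 3.03-fold higher, and the erythroid list at 0.55 (percentile 98.5), with Hba-a1 5.40-fold higher; over probes above background on both arrays the erythroid median was 0.23 (percentile 88.9). Immediate early genes were at -0.60 (percentile 0.01), with Jund 3.23-fold lower and Egr3 3.87-fold higher. Of 20 measured, however, 5 were at least 2-fold higher and 3 lower. Ribosomal protein genes were at -0.28 (percentile 0), apoptosis regulators at -0.57 (percentile 1.13), with Casp9 5.06-fold lower and Bcl2l1 7.09-fold higher, and the mast cell, basophil and eosinophil list at -0.74 (percentile 0.41), with Epx 8.47-fold lower (-0.21, percentile 29.0, with no filter on dim probes). Of the Bcl2l1 probes, 1 was not above background in WT, so its fold may rest in part on the floor.

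Among genes above background in both arrays on every compared probe and meeting the naming rule, the largest single differences of the double mutant against WT were Ufsp1 (34.4-fold), Med13l (31.4-fold), Eef1e1 (20.9-fold) and Slc4a1 (20.1-fold) on the higher side, and Klf9 (23.5-fold), Smarca2 (22.1-fold), Slc2a9 (21.5-fold) and Mamld1 (21.2-fold) on the lower side. Xist, which has 1 probe below background in the double mutant, was 137-fold lower on the other. Below background in 1 array, S1pr3 was at least 72.1-fold higher and Pcbp3 at least 45.3-fold lower. In all, 2273 genes were at least 2-fold higher and 2455 lower among 14817; with normexp the counts were 806 and 978, and weeks after transplantation differed.

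Against JAK2V617F, the double mutant gives the TET2KD difference on the JAK2V617F background, with weeks after transplantation differing too (13 and 16). Mature neutrophil genes were higher (median 1.63, percentile 100; 12 of 18 at least 2-fold higher), with Lcn2 7.02-fold and Ltf at least 13.3-fold higher. Genes of multipotent progenitors and lymphoid priming were higher (median 1.27, percentile 100; 7 of 13), with Cd52 5.05-fold, Ccr9 at least 9.29-fold and the interleukin 7 receptor gene Il7r at least 15.2-fold higher. The Hoxa and cofactor list was lower (median -1.23, percentile 0.03; 7 of 11 at least 2-fold lower), with Hoxa3 4.28-fold and Meis1 3.86-fold lower and Hoxa6 6.14-fold higher; with no filter on dim probes the list was inside the range (-0.48, percentile 4.41).

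Granulocyte and monocyte progenitor genes were at 0.39 in the double mutant against JAK2V617F (percentile 99.9), with Fcgr3 5.82-fold higher. The macrophage and dendritic cell list was at 0.59 (percentile 100), with H2-Eb1 3.52-fold higher and Vcam1 at least 7.33-fold lower; with no filter on dim probes it was inside the range (0.14, percentile 95.01). Inflammatory cytokine genes were at 0.33 (percentile 98.0), with Relb 3.90-fold higher, but inside the range with normexp (0.15, percentile 93.3). Megakaryocyte and platelet genes were at -0.40 (percentile 2.41), with Pf4 4.40-fold lower, a position kept under 2 of 8 alternatives, and ribosomal protein genes at -0.13 (percentile 1.67), kept under 3 of 8. Among genes above background in both arrays and meeting the naming rule, the largest single differences were Hba-a1 (25.8-fold), Slc4a1 (23.1-fold) and Tbx21 (15.2-fold) on the higher side and Stard10 (24.0-fold), Actr1b (23.8-fold) and Rtl5 (19.7-fold) on the lower side. Below background in 1 array, H2-DMb2 was at least 69.0-fold higher and Bsn at least 69.6-fold lower; Xist was 47.9-fold lower on its brighter probe. In all, 1838 genes were at least 2-fold higher and 1909 lower among 14981; with normexp the counts were 480 and 618.

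Against TET2KD, the double mutant gives the JAK2V617F difference on the TET2KD background, with weeks after transplantation differing too (13 and 10). Granulocyte and monocyte progenitor genes were higher (median 1.23, percentile 100, 10 of 19 at least 2-fold higher), with F13a1 at least 7.98-fold and Fcgr3 4.52-fold higher. Mature neutrophil genes were at -0.47 (percentile 1.44), with Ltf 2.06-fold lower but Mmp8 2.60-fold and Fpr1 at least 4.55-fold higher. Of 18 neutrophil genes, 1 was at least 2-fold lower and 3 higher. With 1 probe drawn per gene the neutrophil list was inside the range (-0.23, percentile 10.98). Cell cycle genes were higher: S phase genes were at 0.70 (percentile 100), with Gins2 5.77-fold higher, and those of G2 and mitosis at 0.72 (percentile 99.9), with Aurka 13.3-fold higher and Cenpf at least 10.4-fold lower. The stem cell list was lower (median -0.68, percentile 0.03), with Txnip 7.33-fold and Meis1 4.78-fold lower. Respiratory chain genes were at 0.67 (percentile 100), with Ndufs3 2.94-fold higher.

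Immediate early genes were at -0.65 in the double mutant against TET2KD (percentile 0), with Ier2 2.80-fold and Klf6 2.75-fold lower and Egr3 15.7-fold higher. Megakaryocyte and platelet genes were at -0.73 (percentile 0.12), with Vwf 5.38-fold lower and Gata1 9.65-fold higher, and plasma cell genes at -0.95 (percentile 0.91), with Sdc1 4.17-fold lower, but inside the range over probes above background on both arrays (-0.53, percentile 6.9). Glycolysis and hypoxia genes were at 0.55 (percentile 99.9), with Ldha 2.31-fold higher and Ddit4 5.16-fold lower, and p53 targets at 0.80 (percentile 99.3), with Tigar 9.87-fold higher, Plk2 7.44-fold lower and Perp at least 17.1-fold lower. Cytokine receptors were at 0.47 (percentile 99.3), with Il6st 8.01-fold higher; their median was -0.00 over probes above background on both arrays. Among genes above background in both arrays and meeting the naming rule, the largest single differences were H2-DMb2 (31.2-fold), Wdtc1 (27.8-fold) and Mrpl58 (20.8-fold) on the higher side and Klf9 (30.5-fold), Arfgef2 (26.8-fold) and Zfp951 (24.3-fold) on the lower side. The folds of Wdtc1 and Arfgef2 leave out a probe not above background in either array. Below background in 1 array, Smim13 was at least 42.3-fold higher and Aqp3 at least 42.9-fold lower. In all, 2297 genes were at least 2-fold higher and 2264 lower among 14565; with normexp the counts were 891 and 807, and with the series matrix values 2966 and 2263.

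**Figure D3:**
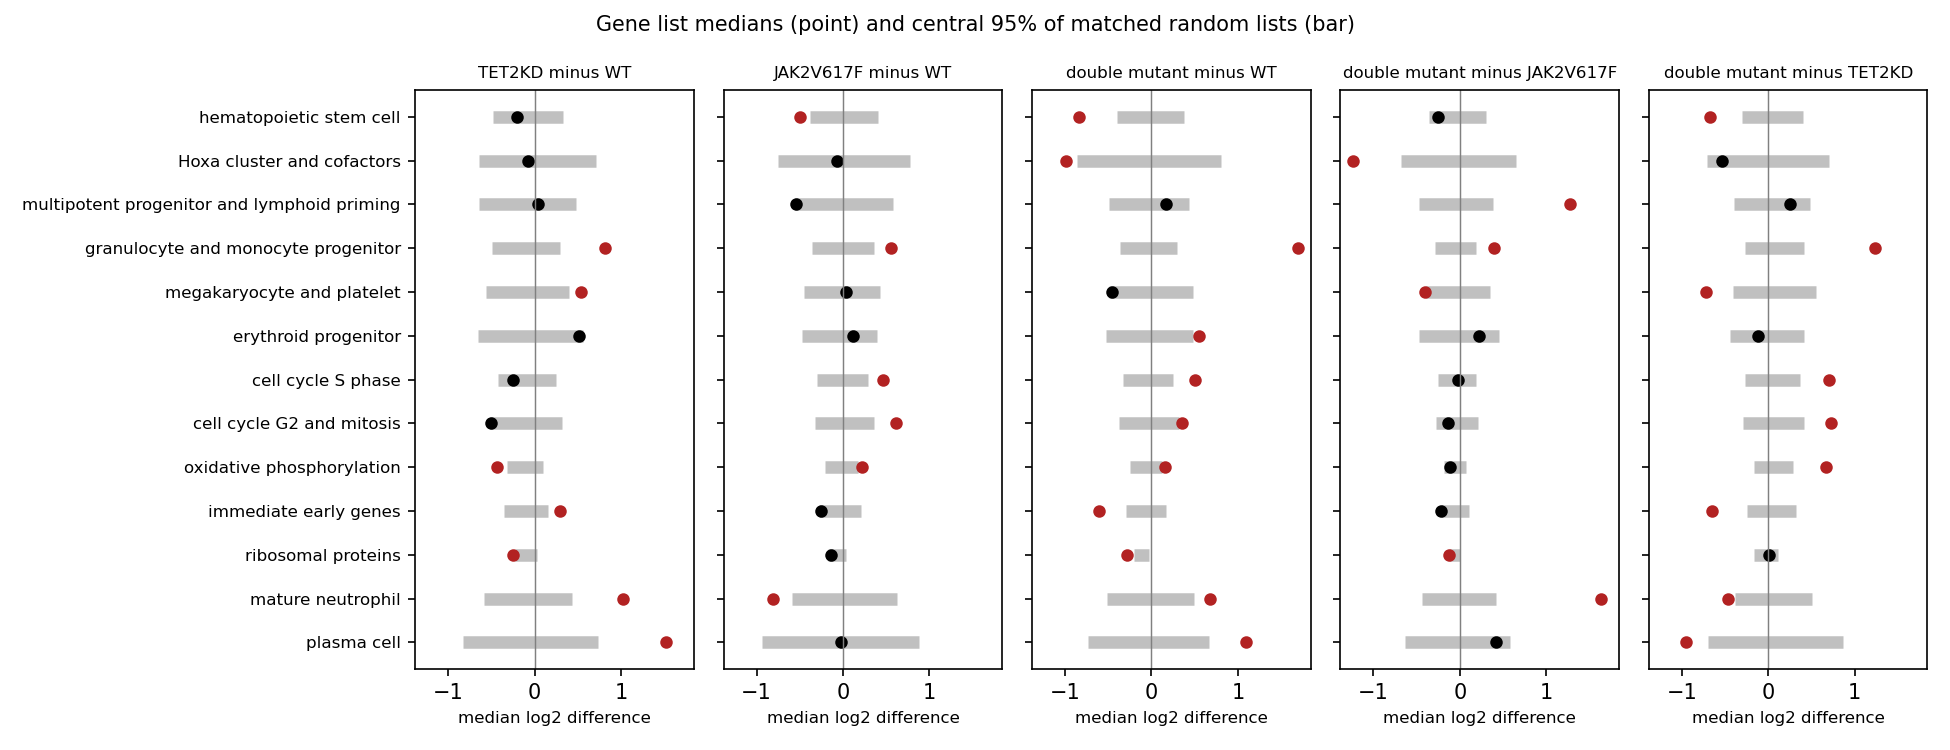
Median log2 difference (x axis) of 13 gene lists (y axis) in the 5 comparisons, with the central 95% of matched random lists as grey bars; red points lie outside it. The progenitor list lies above the bar in all 5 panels, with medians from 0.39 to 1.70.

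The 2 backgrounds were set against each other over 10567 genes above background on all 4 arrays, in pairs of differences that share no array. Gene by gene, the JAK2V617F difference on WT had a Pearson correlation of 0.12 with that on TET2KD (Spearman 0.12), and the TET2KD difference on WT had 0.03 with that on JAK2V617F (Spearman 0.03). In the 2642 brightest of these genes the Pearson values were 0.29 and 0.08. For JAK2V617F, 302 genes were at least 2-fold higher and 313 lower on both backgrounds, where independent lists would share 172 and 157; 384 genes went opposite ways, where independent lists give 329. For TET2KD the shared genes were 173 and 212 against 108 and 149, and 384 against 255 went opposite ways. Opposite genes thus also exceeded the independent number, so the excess of shared genes does not by itself show a common TET2KD response. The arrays of JAK2V617F and the double mutant had the highest correlation of any pair, 0.93, and the other pairs 0.89 to 0.90.

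Among genes above background on all 4 arrays and meeting the naming rule, the interaction (double mutant minus both single mutants plus WT) was largest on the lower side for Hdac8 (-7.61 on the log2 scale), Lysmd1 (-6.81) and Atp7a (-6.72) and on the higher side for Lrrc75a (6.67), Tbc1d2b (6.55) and Pdzd2 (6.19). Among the lists it was -0.82 for megakaryocyte and platelet genes (percentile 0.34), -0.35 for immediate early genes (percentile 0.15), 0.38 for respiratory chain genes (percentile 99.2) and 0.83 for multipotent progenitor and lymphoid priming genes (percentile 98.6). It was 0.17 for ribosomal protein genes (percentile 98.4), 0.84 for the macrophage and dendritic cell list (above the range) and 0.75 for the mast cell, basophil and eosinophil list (percentile 98.5). It was -0.11 for granulocyte and monocyte progenitor genes (percentile 23.1) and -0.18 for stem cell genes (percentile 15.5), inside the range. Over the 5 comparisons, 56 of 165 list medians lay outside the range, where 8.25 would be expected if genes were independent.

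An additive fit of both lesions over the 4 arrays, added after seeing the data, leaves 1 residual degree of freedom per gene and counts any interaction as noise. Both arrays with TET2KD were taken at fewer weeks (10 and 13) than both without (16), so weeks are confounded with the TET2KD effect. With limma, 0 of 10567 genes passed an adjusted p of 0.05 for TET2KD or for JAK2V617F; the smallest adjusted p was 0.130 and 0.211. At an unadjusted p under 0.05 there were 644 genes (6.09%) for TET2KD and 980 (9.27%) for JAK2V617F.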

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

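The tests of brightness, neutrophils and weeks in this part were chosen after the result was seen; those of probe pairs and of loess were set before their own results, but after the patterns and the probes of 34 genes had been looked at. The results listed next went opposite ways on the 2 backgrounds, each at least 2-fold for a gene or outside the range of random lists for a list. With 1 array per group, the difference between backgrounds was not tested over replicates; for lists it was only set against random lists, over genes above background on all 4 arrays. The values are the second background minus the first, on the log2 scale. Each difference uses the probes above background in 1 of its own 2 arrays, so the value of a gene with several probes (Hdac8, Ppp3cc) can differ from its interaction or between the lesions.

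For TET2KD, the megakaryocyte and platelet list was at 0.53 on WT and -0.40 on JAK2V617F, a difference of -0.93 (interaction -0.82, percentile 0.34, outside the range); the first is 0.01 with no filter on dim probes and inside the range with 1 probe per gene (0.39), and the second stays outside the range under 2 of 8 alternatives. For JAK2V617F, the cytokine receptor list was at -0.42 on WT and 0.47 on TET2KD, a difference of 0.88, which the interaction over 20 receptors above background on all 4 arrays does not bear out (0.21, percentile 74.11, inside the range); the first is inside the range with the brightest probe, and the second stays outside under 4 of 8 alternatives and is -0.09 with 1 probe per gene. Genes below background on 1 or 2 of the arrays are set to the floor there, and their differences are at least as large as given, except for Ppp3cc. The named genes were chosen for large differences on these same arrays. How many would go opposite ways by chance was not computed, so the counts that follow show no response by themselves. Second minus first is the same combination of the 4 arrays for either lesion, so a gene listed under both is 1 result. Of 51 genes named for TET2KD, 11 went opposite ways. Above background on all 4 arrays, the difference was 6.13 for Bcas3os2, 5.20 for Ace, -7.21 for Hdac8, -6.17 for Actr1b and -4.89 for Aph1b. As bounds set by the floor, it was 8.37 for Tac4, 7.82 for Dusp22, -6.91 for Stard10, -6.78 for Egr4 and -6.56 for Rtl5. Of 52 genes named for JAK2V617F, 15 went opposite ways. Above background on all 4 arrays, the difference was 6.67 for Lrrc75a, -6.47 for Med13l and -5.57 for Hsdl1. As bounds set by the floor, it was 8.37 for Tac4, 7.35 for Slc2a4rg-ps, 7.06 for H2-DMb2, 6.41 for Smim13, 5.94 for Zfp456, -8.41 for Fzd6, -7.31 for Tas2r143, -6.56 for Rtl5, -6.26 for Tnfsf14, -6.25 for Lfng and -5.12 for Nup214. For Ppp3cc the values were 8.72 for TET2KD and 8.30 for JAK2V617F; the second difference averages a further probe that the first lacks, so they are not bounds.

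About 3 in 10 genes differed 2-fold between single arrays (31.2% to 33.4% against WT). A candidate explanation is noise specific to a probe's stretch of cDNA, from amplification, labelling or cross-hybridization: the Spearman correlation between 2 probes of one transcript at least 500 bases apart was at lowest 0.058 over the 3 mutants against WT, under the bound of 0.3 set before. Sampling of few RNA molecules stays open, since the SD over the 2642 dimmest genes was at lowest 1.48 times that over the 2642 brightest, between the bounds that would have decided it. Genotype also stays open as untested: pairs of distant probes that both differed 2-fold the same way numbered 101 in TET2KD against WT, where shuffled pairs gave 77.8 on average (95% range 63 to 93). The shuffle did not keep pairs of like brightness together, so this excess does not by itself show a genotype effect.

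Granulocyte and monocyte progenitor genes were higher in the double mutant than in TET2KD (1.23) and than in WT (1.70). Mature neutrophils carried along in the sort, which a Sca-1 and c-Kit gate with lineage depletion should remove, would raise neutrophil genes at least as much. Against TET2KD the neutrophil median minus the progenitor median was -1.70 (bootstrap range over genes -2.37 to -0.38), which argues against them on these 2 arrays. S100a8 and S100a9, named outside the rule, were 1.61-fold and 1.66-fold lower. Of 18 neutrophil genes, however, 1 was at least 2-fold lower and 3 higher. With 1 probe drawn per gene the medians were -0.23 (percentile 10.98, inside the range) and 0.89. The bootstrap treats the genes of 1 pair of arrays as independent and leaves out variation between sorts and animals. Against WT the neutrophil median minus the progenitor median was -1.02 (-2.10 to 0.13), so neutrophils cannot be told apart from a change within the gate there, because the range includes 0. In TET2KD against WT and in the double mutant against JAK2V617F the neutrophil median was above the progenitor median (1.02 and 0.81, 1.63 and 0.39). Mature neutrophils in the sort stay open there and were not tested. Weeks after transplantation alone, as a steady trend, would put TET2KD, the array furthest from WT in weeks, at least as high as the double mutant. The median of 1.23 over TET2KD goes against such a trend on these arrays. That value was already seen when the test was chosen and rests on 1 array per group, so it cannot exclude an effect of weeks. Genotype or another cell mix within the gate may also remain.

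Cell cycle genes were higher and stem cell genes lower with JAK2V617F on both backgrounds, in pairs of arrays that share none. After cyclic loess, 6 of the 6 medians stayed outside the range of random lists on the same side. The random lists were already matched on mean expression, so an intensity-dependent bias between arrays would shift them along with a list. Staying outside was thus close to fixed in advance, and the loess test says little about such a bias. JAK2V617F and WT were both taken at 16 weeks, so weeks after transplantation do not separate those 2 arrays by design. For the double mutant against TET2KD, weeks and genotype are confounded. That JAK2V617F itself underlies the pattern may be taken as a hypothesis only, with 1 array per group.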

How the results depend on the processing

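The 1-probe list test, the check of the floor and the additive fit were chosen after seeing the data; the other alternatives were chosen before. Signal over background limits the counts: 2650 to 3008 genes per comparison were below background on 1 of the 2 arrays. Normexp with its offset shrinks differences of dim probes by construction, and the counts of genes higher and lower became 796 and 1082 (TET2KD against WT), 886 and 910 (JAK2V617F against WT), 806 and 978 (double mutant against WT), 480 and 618 (double mutant against JAK2V617F) and 891 and 807 (double mutant against TET2KD). A 3-fold threshold gave, in the same order, 1180 and 1268, 1158 and 1172, 1089 and 1245, 792 and 872, and 1046 and 1104. Only probes above background on both arrays, which leaves fewer genes, gave 1419 and 1661 for TET2KD, 1438 higher for JAK2V617F and 1390 higher for the double mutant against WT, 1178 and 1255 against JAK2V617F, and 1500 and 1497 against TET2KD. With the series matrix values the counts were 2218 and 3086 for TET2KD against WT and 2966 and 2263 for the double mutant against TET2KD, a less even split. That alternative takes the floor of dim probes from probe averages, which puts it at -3.64 in TET2KD against -2.79. With the floor taken from spots the same values gave 2235 and 2542, and 2378 and 2183, so most of the change comes from the floor. The counts of the comparisons carry the same dependence: with the floor from probe averages those 2 pairs of counts became 2255 and 3042, and 2882 and 2337. No filter on dim probes, which adds genes, gave 3781 lower for the double mutant against WT, and 2821 higher and 3122 lower against JAK2V617F.

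The correlation of the JAK2V617F differences was 0.157 with normexp and 0.0890 with no filter, and the spot SD was 0.117 with normexp, against 0.159 over the 4 arrays; the cause was not tested. List medians outside the range numbered 52 to 61 of 165 under these alternatives. With 1 random probe per gene, 51 of the 56 stayed outside on the same side; the mature neutrophil list in the double mutant against TET2KD did not (median -0.23), nor did cytokine receptors in that comparison (-0.09), megakaryocyte and platelet genes (0.39) and endothelial genes (0.63) in TET2KD against WT, or ribosomal protein genes in the double mutant against JAK2V617F (-0.12). The additive fit gave 0 genes for both lesions under each of the 7 scaling, background, filter and probe alternatives tried with it.

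Values that changed sign were the cytokine receptor median in the double mutant against TET2KD with probes above background on both arrays (-0.002452), Bcl2l1 in TET2KD against WT with that filter and with the brightest probe (-0.62 in both), where its 2 probes disagree, and Csf1r in the double mutant against JAK2V617F with the brightest probe (-0.003375). That cytokine receptor median also changed sign with 1 probe drawn per gene (-0.09). Of the other values of single genes, 2257 stayed within the SD of a spot difference (0.225) and 489 moved by more; of list medians, 1207 stayed within the SD of random lists and 110 moved by more. No paired analysis was possible because each group has 1 array.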

Other observations

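Eosinophil granule genes, chosen after their values were seen, were lower in both arrays with JAK2V617F. Epx was 18.0-fold and Prg2 7.46-fold lower in JAK2V617F than in WT, and 8.47-fold and 3.45-fold lower in the double mutant than in WT. The mast cell, basophil and eosinophil list they belong to was at -0.25 in JAK2V617F against WT (percentile 16.0), inside the range, and at -0.74 in the double mutant. Hba-a1, also chosen after its values were seen, was 15.1-fold higher in TET2KD and 4.77-fold lower in JAK2V617F than in WT. Hbb-b2 was 4.61-fold and 3.34-fold higher in the same arrays, and the erythroid list was inside the range in both (0.51, percentile 96.7; 0.12, percentile 72.1).

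Xist, the X-inactivation transcript of female cells, had scaled log2 signals of 5.57 in WT, 1.62 in TET2KD, 4.05 in JAK2V617F and -1.53 in the double mutant on its brighter probe. The Y-linked gene Eif2s3y was above background on all 4 arrays, at -0.69, -0.93, -2.92 and -0.87. Ddx3y was above background on all arrays but WT, and Uty only in WT and JAK2V617F. X and Y genes thus give no single picture of the sex of the cells, which the labels used here do not give. Xist was lower in the arrays with TET2KD than in those without, with an additive effect of -4.76 on the log2 scale. Its other probe was above background only in WT and JAK2V617F. A difference in the sex of the cells could therefore be confounded with TET2KD, which was not tested.

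Genes carried by 2 probes at least 500 bases apart, a selection made after seeing the data, include Txnip, which was 9.30-fold and 4.03-fold lower in JAK2V617F than in WT and 11.2-fold and 10.5-fold lower in the double mutant than in WT. In the double mutant against TET2KD its probes were 4.98-fold and 10.8-fold lower. Wdfy1 was 5.10-fold and 5.27-fold lower in TET2KD and 6.37-fold and 12.6-fold lower in the double mutant, both against WT. Smad3 was 5.51-fold and 4.47-fold lower in JAK2V617F than in WT. Shuffled pairs give most of the number of such genes in each comparison, so a single gene on this list is no finding by itself.

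By array, genes at least 2-fold above all other arrays numbered 400 in WT, 331 in TET2KD, 214 in JAK2V617F and 193 in the double mutant, and genes at least 2-fold below all others 379, 453, 200 and 254, over 10567 genes.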
